A study of Mus musculus with 6 samples.

How the data were processed

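RNA from 3 samples of aggregated primary mouse Sertoli cells and 3 samples of aggregated MSC-1 cells was labelled with biotin and hybridised to Affymetrix arrays, with 10 µg of RNA per sample, per the labels' protocols. The deposited value table holds a linear signal intensity for each of 45101 probe sets on each array. GCOS is named in the submitters' processing notes. Its version, background method and target value are not given in the sources used here. The deposited intensity values were already scaled between arrays, since their mean between the 2nd and 98th percentiles was 125.0 on every array. The authors' deposited table of 4-fold changes holds a signed fold, positive where primary cells were higher, and a gene symbol per probe set. How the authors computed these folds is not given in the sources used here. They are not the ratios of the value table's group means, so folds and differences in the report come from the value table.

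Gene symbols were taken from the authors' deposited table, since no other annotation of the probe sets was used here. Of its 3198 probe sets, 50 had no symbol, 79 had several and 3069 had a single symbol. A symbol was current in the GRCm38.p6 RefSeq gene table for 2445 probe sets, was updated through a unique synonym for 425 and was kept as written for 199. These named 2329 genes, 531 of them with several probe sets. A gene was represented by its probe set with the highest mean, and the probe sets of Pias2, Xaf1 and Alcam disagreed in direction. No genomic coordinates are given.

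The values were analysed as log2(signal + 16), which understates the change of dim probe sets, without further scaling or a filter. After removal of 64 control probe sets, 45037 were fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a trend in the prior variance), with group as the factor. Tests were 2-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The plan adjusted gene p-values over the genes tested. Because names existed only for probe sets chosen by the authors, the adjustment was made over all probe sets. SE denotes the moderated standard error of a log2 difference, and signals are means ± SD over 3 arrays.

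An array's background was set at the highest of 27 bacterial control probe sets with no target in the sample, 7.70 to 15.8. Where a probe set lay at or below this on all 3 arrays of a group, the fold is given as "at least", from the mean log2 signal of the brighter group against the mean of the higher of background and signal. The ratio of 3' to 5' signals was 1.42 to 1.63 for Actb and 0.785 to 0.831 for Gapdh.

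A total of 22 gene lists with 575 genes were fixed before the data were examined, and 129 of these genes were named. Some lists shared genes, such as Clu, Serping1 and Tnfrsf11b, so their results are not independent of each other. Lists with at least 3 named members were tested with limma's camera at a preset correlation of 0.01, with an estimated correlation and fry as alternatives. The rule for genes named in the text was also fixed then. It took the 6 highest and 6 lowest log2 differences among genes past the threshold with non-overlapping groups, up to 2 members per list and direction past the threshold, and fixed Sertoli cell genes, among them Sox9, Wt1, Gata4, Amh, Clu and Fshr, whatever their result. Some results under this rule are not reported here. Groups did not overlap for 51.2% of probe sets, where chance gives 10%.

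Alternatives were pseudocounts of 1 and 64, quantile and median scaling, removal of the dimmest 40% of probe sets, the mean of a gene's probe sets, a prior without trend, the replicate number as a block, each array left out, and limma's treat against a 2-fold change. The test was tried on simulated data for this comparison with 45037 probe sets. It recovered 44 of 100 probe sets changed 2-fold and 88 of 100 changed 4-fold, and 5.04% of its calls were false. The changed probe sets were all brighter than the median, so dim ones were not tried. They were also a far smaller share than the 40.9% that passed in the real data, on which recovery depends. Figures were drawn with matplotlib 3.10.9.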

Results

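Gene expression was measured in mouse Sertoli cells, the somatic cells of the seminiferous tubule that nurse germ cells and shield them from the immune system. Affymetrix oligonucleotide arrays compared 3 samples of primary Sertoli cells with 3 samples of MSC-1 cells, a mouse Sertoli cell line immortalised by a viral large T antigen. Both kinds of cell were cultured for 48 h at 37 °C as aggregates before RNA was taken. The donors of the primary cells were 10 to 20 days old in the growth protocol and 19 to 20 days old in the design text. The comparison addresses which transcripts differ between Sertoli cells used for transplantation and the line, with immune privilege, the protection of grafted cells from rejection, as its theme. The median signal was 29.8, 27.2 and 29.2 on the primary Sertoli cell arrays and 23.1, 24.4 and 24.7 on the MSC-1 arrays, in the deposited linear units. Signals exceeded the array's own no-target controls for 73.1% to 74.8% of probe sets in primary cells and for 57.0% to 66.7% in MSC-1 cells. The cutoff, the highest control, was 7.70 to 7.89 on the primary arrays but 14.4, 15.8 and 8.97 on the MSC-1 arrays. The median control was alike, at 1.37 to 1.74 and 1.33 to 1.87. The cutoff was therefore stricter for MSC-1 cells, and the shares do not compare like with like. The number of arrays, 3 per group, limits the precision of every value below. Nothing in the labels says that the replicates came from separate cultures or animals, so the p-values measure only the spread between these samples, which may be technical.

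Primary Sertoli cells and MSC-1 cells differed widely. Of 45037 probe sets, 18418 (40.9%) passed an adjusted p of 0.05 in limma, with 8676 higher in primary cells and 9742 higher in MSC-1 cells. Signals changed at least 4-fold on the log2(signal + 16) scale for 2810 probe sets, 2003 of them higher in primary cells and 807 higher in MSC-1 cells. With a pseudocount of 1 the 4-fold counts were 4067 and 1762, and with 64 they were 963 and 337. Setting the arrays to a common median moved the share of changed probe sets that were higher in primary cells from 47.1% to 35.0%, and shifted the median log2 difference of all probe sets by -0.16. The correlation of log2 signals across probe sets, which are not independent replicates, was 0.816 to 0.828 between groups, 0.985 to 0.989 within MSC-1 cells and 0.965 to 0.987 within primary cells. Primary replicate 1 took part in the lowest correlations of its group.

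Gene names were available for the probe sets in the authors' deposited table of 4-fold changes, which lists 3198 probe sets, 1902 higher in primary cells and 1296 higher in MSC-1 cells. In the value table all 3198 differed in the listed direction and 3197 passed the test. These probe sets named 2329 genes, of which 1437 were higher in primary cells, 891 were higher in MSC-1 cells and 1, the transcription factor gene Dmrt2, did not pass (log2 difference -0.94, SE 0.36, adjusted p = 0.0658, named after its value was seen). Because the authors chose the table on these samples, the direction of a named gene is not independent evidence, and a gene outside the table was not analysed here. A further 392 probe sets outside the table changed at least 4-fold and stay unnamed.

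The genes with the highest excess in primary cells included transcripts typical of developing sperm. Tcte3, a dynein light chain gene expressed in testis, had a signal of 6825 ± 255 (SD, n = 3) in primary cells and 24.1 ± 24.1 in MSC-1 cells, a log2 difference of 7.57 (SE 0.34). The uncharacterised transcript 1700010I14Rik differed by 6.39 (SE 0.18). The other 4 genes at this end were at background on all MSC-1 arrays, which gives only a lower bound and no order among them. Pgam2, the muscle and testis form of phosphoglycerate mutase, was at least 149-fold higher in primary cells, and Hspb9, a small heat shock protein gene of the testis, at least 108-fold higher. The uncharacterised transcripts 1700018B24Rik and 1700066D14Rik were at least 197-fold and 153-fold higher. The highest adjusted p among these genes was 9.25e-07, for Tcte3.

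The genes with the highest excess in MSC-1 cells included genes of glia and pigment cells. Mbp, which encodes myelin basic protein, had a signal of 2987 ± 1478 (SD, n = 3) in MSC-1 cells and 9.70 ± 2.53 in primary cells, a log2 difference of -6.77 (SE 0.29). Sox10, a transcription factor gene of neural crest derivatives, differed by -5.79 (SE 0.18), with signals of 1570 ± 81.2 and 13.2 ± 7.04. Dct, the melanin pathway enzyme dopachrome tautomerase, differed by -5.00 (SE 0.16). Adh7, an alcohol dehydrogenase gene, differed by -5.75 (SE 0.34), the plexin gene Plxnb3 by -4.88 (SE 0.25) and Agt, which encodes angiotensinogen, by -4.79 (SE 0.49). The highest adjusted p among these 6 genes was 9.34e-05, for Agt, whose signal in primary cells came mainly from replicate 1 and whose difference was -5.46 without that array.

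Sertoli cell markers went both ways. Of 39 genes on this list, 11 were named, 7 higher in primary cells and 4 higher in MSC-1 cells. Cst12, a cystatin gene, differed by 5.63 (SE 0.43) on the log2 scale, and Aard was at least 46.7-fold higher in primary cells. Clusterin, Clu, an abundant secreted Sertoli product, had signals of 4554 ± 985 and 493 ± 93.3 (SD, n = 3), a difference of 3.16 (SE 0.18), and the sex-determining factor Sox9 differed by 2.01 (SE 0.22). Cst12 and Sox9 were lowest on primary replicate 1, at 661 against 2318 and 1891 and at 131 against 204 and 244. Clu was highest there, at 5623 against 3683 and 4355. Higher in MSC-1 cells were transferrin, Trf, with -3.22 (SE 0.17), and prostaglandin D2 synthase, Ptgds, with -2.92 (SE 0.33). Wt1, Gata4, Amh and Fshr were not analysed here because the authors' deposited table does not name them. The list's median was 3.16, and camera gave an adjusted p of 0.971 against the other named genes. The median log2 level of the named members was 8.62, 9.16 and 8.59 on the primary arrays and 5.55 to 5.80 on the MSC-1 arrays.

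Genes of cell junctions and of the basement membrane were also split. For junction and blood-testis barrier genes, 4 of 37 were named, 2 in each direction. Gja1, the main gap junction connexin of Sertoli cells, was at least 51.6-fold higher in primary cells, and the adhesion gene Nectin3 at least 10.2-fold higher, both with MSC-1 signals at background. The Gja1 signal was 1012 on primary replicate 1, the array with the highest fibroblast and myoid marker levels, and 478 and 579 on the other primary arrays. Jam2, a junctional adhesion molecule gene, and the polarity gene Pard3 were higher in MSC-1 cells, with log2 differences of -1.96 (SE 0.33) and -2.01 (SE 0.27). For basement membrane and matrix genes, 9 of 26 were named, 4 higher in primary cells and 5 higher in MSC-1 cells. Col18a1, with a signal of 457 on primary replicate 1 and 212 and 225 on the others, and Nid1 differed by 3.22 (SE 0.27) and 2.95 (SE 0.22), while Timp2 and the laminin gene Lama4 differed by -2.79 (SE 0.13) and -2.59 (SE 0.21). Camera's adjusted p was 0.912 for junctions, with a median of 0.45 and a downward camera direction, and 0.420 for matrix genes, with a median of -1.74.

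Most named inhibitors of complement were higher in primary Sertoli cells. Of 17 genes on the list, 7 were named, 6 higher in primary cells and 1 higher in MSC-1 cells. Serping1, the C1 inhibitor, was at least 59.2-fold higher in primary cells, at 834 ± 462 against 7.76 ± 0.954 (SD, n = 3). Its signal was 1337 on primary replicate 1, where fibroblast and myoid marker levels were also highest, and 738 and 429 on the other primary arrays. Thbd, which encodes thrombomodulin, was at least 24.4-fold higher. Cd59a, which blocks the membrane attack complex, was the exception, with 98.5 ± 25.2 in primary cells and 858 ± 49.5 in MSC-1 cells, a log2 difference of -2.95 (SE 0.16). The list's median was 3.16, that of Clu, which is also on the Sertoli cell marker list and is its median. Camera gave an adjusted p of 0.420. Complement components and receptors had 4 of 29 genes named, 2 in each direction, with a median of -0.04 and an adjusted p of 0.778. C8b, of the terminal complex, was at least 10.1-fold higher in primary cells, and C8g, of the same complex, differed by 2.29 (SE 0.23). C4b, of the activation cascade, differed by -3.29 (SE 0.46), and Masp1 was at least 11.9-fold higher in MSC-1 cells. Without MSC-1 replicate 2, C4b differed by -3.90.

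Serine protease inhibitors followed a like count. Of 36 serpins and other serine protease inhibitors, 10 were named, 8 higher in primary cells and 2 higher in MSC-1 cells, with a median of 3.33 and a camera adjusted p of 0.420. Spink2, an inhibitor of the sperm acrosome, led with 1870 ± 248 against 10.6 ± 1.01 (SD, n = 3), a log2 difference of 6.14 (SE 0.13). Serpinb9, an inhibitor of granzyme B, differed by 3.74 (SE 0.34), with a signal of 1443 on primary replicate 1, the array with the highest fibroblast and myoid marker levels, and 649 and 537 on the others. Serpinf1, which encodes pigment epithelium-derived factor, and Serpine2 were higher in MSC-1 cells, with -3.21 (SE 0.16) and -2.54 (SE 0.48). Without primary replicate 1, Serpine2 differed by -3.15.

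Secreted and surface immune regulators had 11 of 43 genes named, 7 higher in primary cells and 4 higher in MSC-1 cells. Ptgs2, the inducible cyclooxygenase, was at least 49.1-fold higher in primary cells, and the galectin gene Lgals3 differed by 3.76 (SE 0.36). Both were highest on primary replicate 1, as fibroblast and myoid markers were, at 1022 against 466 and 506 for Ptgs2 and 1186 against 391 and 500.2 for Lgals3. The constitutive cyclooxygenase gene Ptgs1 was higher in MSC-1 cells, with -3.06 (SE 0.49), or -3.70 without primary replicate 1. Tnfrsf11b, the decoy receptor osteoprotegerin, was at least 44.7-fold higher in MSC-1 cells, at 350 ± 19.5 against a background signal of 4.35 ± 1.86 (SD, n = 3). Its other listed probe set, which represents it without MSC-1 replicate 2 (-2.83) or replicate 3 (-2.65), differed by -2.70 (SE 0.19). The median was 2.65, with a camera adjusted p of 0.971. Of 32 apoptosis inhibitors, 6 were named, 3 in each direction, with a median of 0.32, a downward camera direction and an adjusted p of 0.708. The chaperone gene Hspa1a was at least 16.7-fold higher in primary cells, with 326 on primary replicate 1 against 156 and 186, and Xiap, a caspase inhibitor, differed by -1.81 (SE 0.16).

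Of 48 chemokines and cytokines, 14 were named, 12 higher in primary cells and 2 higher in MSC-1 cells. Il6 had signals of 877 ± 301 and 20.7 ± 14.2 (SD, n = 3), a log2 difference of 4.62 (SE 0.31), and the neutrophil chemokine Cxcl2 differed by 4.47 (SE 0.37). Cxcl10, an interferon-induced chemokine, and Il18 were higher in MSC-1 cells, with -2.51 (SE 0.24) and -1.43 (SE 0.22). Of 40 interferon-stimulated genes, 5 were named, 4 of them higher in MSC-1 cells. Ifit2 and Mx1 differed by -3.46 (SE 0.20) and -2.79 (SE 0.33), and Ifi44 by 2.60 (SE 0.19) in the other direction. Xaf1, named after its values were seen, was 1 of the 4, but its probe sets disagreed, at -2.37 (SE 0.17) and 3.12 (SE 0.13). The medians were 3.48 and -2.37, the latter being that of Xaf1 and -1.74 with the mean of each gene's probe sets, and camera's adjusted p was 0.297 for both lists. The median log2 level of the chemokine list was 9.29 on primary replicate 1, where fibroblast and myoid marker levels were also highest, and 8.28 and 8.15 on the other primary arrays.

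Antigen presentation was covered thinly. Of 29 genes of class I presentation, the authors' deposited table named H2-Q7, a class Ib gene with near-identical neighbours that the probes may not tell apart, at 332 ± 146 in primary cells and 11.9 ± 5.37 in MSC-1 cells (SD, n = 3). The H2-Q7 signal was lowest on primary replicate 1, at 168 against 449 and 380. The authors' deposited table named 0 of 15 class II genes.

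Of 40 proliferation genes, 21 were named and all 21 were higher in MSC-1 cells, with a median log2 difference of -2.60. Cenpa, the centromeric histone H3 variant, had a signal of 1034 ± 84.4 in MSC-1 cells and 59.3 ± 14.8 in primary cells (SD, n = 3), a difference of -3.82 (SE 0.16). Mcm2, a subunit of the replicative helicase, differed by -3.44 (SE 0.13), and by -2.15 (SE 0.15) in its other listed probe set, which represents the gene when an MSC-1 array is left out (-2.06 to -2.25). Camera with its preset correlation gave an adjusted p of 1.15e-07. The call was lost with an estimated correlation, where the adjusted p was 0.762. Of 26 p53 target genes, 3 were named. Pmaip1, the death gene Noxa, was at least 10.6-fold higher in primary cells, while Phlda3 and Eda2r differed by -1.92 (SE 0.15) and -1.79 (SE 0.23). The list's median was -1.79, with an adjusted p of 0.561.

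Named germ cell and myoid cell markers were all higher in primary cells. Of 26 germ cell markers, 12 were named and all 12 were higher in primary cells, with a median log2 difference of 4.60. Tex101, a germ cell surface glycoprotein, had signals of 1902 ± 377 and 12.0 ± 7.29 (SD, n = 3), a difference of 6.11 (SE 0.22), and Piwil1, of the piRNA pathway, was at least 59.3-fold higher. Camera gave an adjusted p of 0.0197 with the preset correlation, and 0.762 with an estimated correlation. All 4 named myoid cell markers of 12 were higher in primary cells, with a median of 3.74 and a camera adjusted p of 0.297. Tpm2, of smooth muscle, differed by 4.40 (SE 0.27), and Tagln, of the same tissue, was at least 24.6-fold higher.

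Fibroblast, Leydig cell and leukocyte markers were named in small numbers. Of 14 fibroblast markers, 3 were higher in primary cells and 1 was higher in MSC-1 cells, with a median of 3.14 and an adjusted p of 0.778. Col1a2 and Pdgfra differed by 4.84 (SE 0.26) and 3.58 (SE 0.33), and Col6a1 by -2.78 (SE 0.29). Star, which moves cholesterol into mitochondria for steroid synthesis, was the 1 named Leydig cell marker of 12 and differed by 3.89 (SE 0.14). The platelet factor gene Pf4 and the macrophage gene Mpeg1, the 2 named leukocyte markers of 22, differed by 2.74 (SE 0.23) and 2.05 (SE 0.27). The table named 0 of 12 endothelial markers. The median log2 level of the fibroblast list was 9.83 on primary replicate 1 against 8.83 and 8.81 on the others, that of the myoid list 9.35 against 8.48 and 8.43, and that of the germ cell list 8.997 against 9.40 and 9.17.

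The Y-linked genes Ddx3y and Eif2s3y gave no signal above background on any MSC-1 array. Ddx3y, an RNA helicase gene, had a signal of 385 ± 27.5 in primary cells and 2.73 ± 2.55 in MSC-1 cells (SD, n = 3), at least 30.3-fold higher in primary cells. Eif2s3y, which encodes a translation factor subunit, was at least 13.9-fold higher. The list held Y-linked genes and Xist, 5 in all, and Xist was not among the 4 named. All 4 named genes were higher in primary cells, with a median of 2.63 and a camera adjusted p of 0.297.

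Across the 16 lists with at least 3 named genes, proliferation genes and germ cell markers passed camera with the preset correlation, and 0 lists passed with an estimated correlation. Some dimmer groups were above background on part of their arrays, so their differences rest partly on background signals. The MSC-1 signal was above background on 1 of 3 arrays for Tcte3, Cst12, Spink2, Cxcl2, Tpm2, C8g and Pf4 and on 2 of 3 for 1700010I14Rik, Tex101, Il6 and H2-Q7. The primary signal was above background on 2 of 3 arrays for Mbp and Sox10 and on 1 for Agt. In limma's treat against a 2-fold change, run after the data were seen, Il18, Jam2 and Serpine2 did not pass (adjusted p = 0.343, 0.0902 and 0.0648) and the other 67 genes of the naming rule did. Camera set each list against the other named genes, 61.7% of which were higher in primary cells. Every list member given as higher or lower passed both over all probe sets and adjusted over the list alone, which is not independent evidence because the authors chose the table on these samples.

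**Figure D1:**
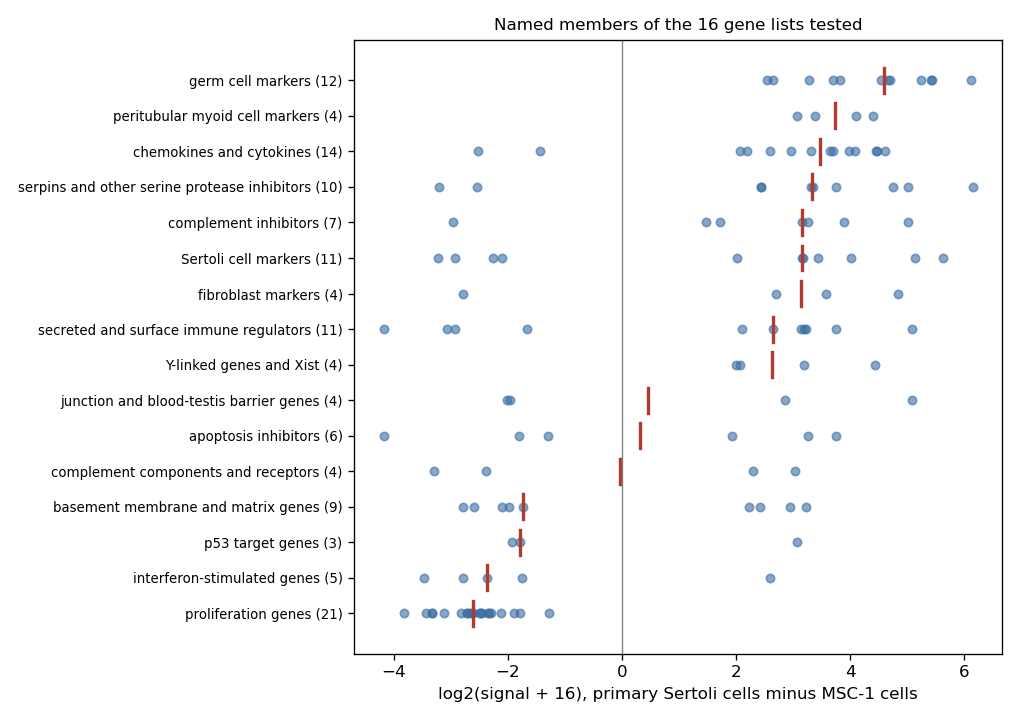
Log2 difference of log2(signal + 16), primary Sertoli cells minus MSC-1 cells (x axis), for the named members of the 16 gene lists tested (y axis, number of named members in brackets). Each point is a gene and each red line the list's median, which ran from -2.60 for proliferation genes to 4.60 for germ cell markers.

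**Figure D2:**
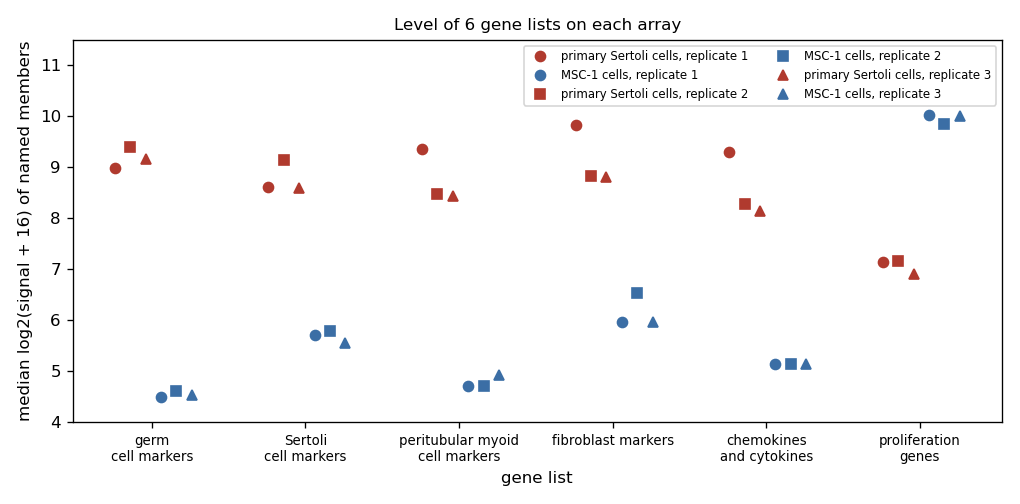
Median log2(signal + 16) of the named members (y axis) of 6 gene lists (x axis) on each of the 6 arrays, with primary Sertoli cells in red and MSC-1 cells in blue. Each point is an array, and the shape gives the replicate number. Primary replicate 1, at 9.83 for fibroblast markers, 9.35 for myoid markers and 9.29 for chemokines and cytokines, lay above the other primary arrays for these 3 lists.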

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

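All alternatives here were chosen before the data were examined, except treat for single genes. The 70 genes named by the rule kept their direction and their side of the threshold under the 14 alternatives chosen beforehand for single genes, and 67 of the 70 passed treat. For gene lists 242 of 256 values stayed on their side of the threshold, 238 of them with camera's direction and the sign of the median also kept. The median of complement components, -0.04, turned to 0.05 with a pseudocount of 64, 0.11 without primary replicate 1 and 0.05 without MSC-1 replicate 3, and camera's direction for immune regulators turned with a pseudocount of 64, none of them called. The count of changed probe sets, 18418, ran from 15058 to 19387 with an array left out. The replicate numbers did not pair the arrays, since the deviations of same-numbered arrays correlated at -0.04, -0.06 and 0.03, and with the replicate number as a block 17204 probe sets passed. Treat against a 2-fold change called 2070 genes. The pseudocount moved the 4-fold counts, as its construction requires for dim probe sets. With 1 there were 5829 probe sets (4067 higher in primary cells, 1762 higher in MSC-1 cells), and with 64 there were 1300 (963 and 337) and 875 genes (643 and 232), against 2810 probe sets and 1768 genes. The median correlation between groups was 0.825, 0.798 with a pseudocount of 1 and 0.682 without the dimmest 40% of probe sets; the cause was not tested. With an estimated correlation, camera no longer called proliferation genes (median -2.60) or germ cell markers (4.60), with an adjusted p of 0.762 for both, since that estimate enters the variance of the test. Before adjustment, camera's p with that estimate was 0.0526 for proliferation genes and 0.244 for germ cell markers, so neither was under 0.05. Fry was run on the named genes alone, of which 2328 of 2329 passed the threshold singly, so its calls are not independent evidence. It asks whether a list's genes move one way on balance and does not compare them with other genes. It called lists that camera did not: Sertoli cell markers (median 3.16), complement inhibitors (3.16), serine protease inhibitors (3.33), immune regulators (2.65), chemokines and cytokines (3.48), interferon-stimulated genes (-2.37), matrix genes (-1.74), myoid markers (3.74), fibroblast markers (3.14) and Y-linked genes (2.63). It gave the opposite direction to camera for junction genes (median 0.45, adjusted p = 0.000385) and complement components (-0.0395, adjusted p = 0.0451). Signals at background limit dim genes to a lower bound of the fold.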

Other observations

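The tests in this part were chosen after the results were seen, except the counts over other splits of the arrays. Several criteria were tried for array scaling and for dimness of the MSC-1 arrays. Those that rested on the listed genes alone cannot decide, because the authors chose these genes by the size of their difference. Values over all probe sets, given below, bear only on a shift of all probe sets in values already scaled between arrays. Named genes were grouped by the stem of their symbol, and 3 of 40 families with at least 5 genes differed in direction from the other named genes (Fisher's exact test, 2-sided, Benjamini-Hochberg). The test treats genes as independent, which genes that move together are not, so the p-values of these families may be too small. All 16 Cfap genes, for cilia and flagella associated proteins, were higher in primary Sertoli cells, with a median log2 difference of 3.77 (adjusted p = 0.00992). Cfap206 and Cfap52 were at background on all MSC-1 arrays and at least 126-fold and 37.0-fold higher in primary cells. Of 30 Ccdc genes, named for coiled-coil domains, 29 were higher in primary cells (median 3.27, adjusted p = 0.000496), among them Ccdc39 and Ccdc40, which are needed to assemble motile cilia. On the same arrays all 12 named germ cell markers were higher in primary cells, with a median of 4.60, as were 149 of 149 probe sets of RIKEN transcripts named for testis clone libraries. All 7 Mcm genes, of DNA replication and meiotic repair, were higher in MSC-1 cells (median -2.65, adjusted p = 0.0159), and 5 of them are on the fixed proliferation list already described. The genes named in this part are a choice made after their values were seen.

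A list of 39 glial, myelin and neural crest genes, drawn up after the ranking was seen, had 24 named members, 20 higher in MSC-1 cells and 4 higher in primary cells. Besides Mbp, Sox10 and Dct, the cadherin gene Cdh19 had 522 ± 88.3 in MSC-1 cells and 5.01 ± 1.95 in primary cells (SD, n = 3). Mitf, the regulator of pigment cells, differed by -4.18 (SE 0.13), the myelin gene Cnp by -3.41 (SE 0.09), S100b, above background on 1 of 3 primary arrays, by -3.85 (SE 0.17) and the myelin protein gene Pmp22 by -3.30 (SE 0.21). Cdh19 and Pax3 were at background on all primary arrays and at least 66.1-fold and 21.6-fold higher in MSC-1 cells. Egr2, above background on 2 of 3 MSC-1 arrays, and Fa2h, also of these lineages, were higher in primary cells by 2.12 (SE 0.19) and 2.74 (SE 0.27), and Ednrb and Ugt8a by at least 4.27-fold and 5.92-fold.

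The germ cell transcripts in the primary arrays may come from germ cells carried along in the preparations. RIKEN transcripts named for adult testis clone libraries, which are in no marker list, were higher in primary cells for 149 of 149 probe sets, against 25 of 53 probe sets of other RIKEN transcripts (Fisher's exact p = 5.53e-20). The test counts probe sets of the same transcript as independent, such as the 3 of 1700010I14Rik, so its p-value overstates the evidence. All these probe sets come from the authors' deposited table, so the shares hold only for that choice. The marker list's median was 4.60 as deposited, 4.52 with quantile and 4.44 with median scaling (SD over members 1.15). The markers alone do not test the authors' array scaling, because all were chosen by their difference. Over all probe sets, however, these scalings moved the median log2 difference by only -0.07 and -0.16. That argues against the choice between the deposited, quantile and median scalings as the source of a median of this size in the named markers. All of these set the arrays to a common level, so scaling as such was not tested. The labels name no purity check, and a loss in the line of transcripts that Sertoli cells themselves make was not tested.

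The glial and neural crest transcripts could come from other cells mixed into the MSC-1 cultures, or from the line itself. The median of the 24 named members was -3.16 as deposited, -3.20 with quantile and -3.32 with median scaling. Neither scaling shrank it, and over all probe sets they moved the median log2 difference by only -0.07 and -0.16. That argues only against the choice between the deposited, quantile and median scalings as the source of a median of this size. The members spread widely (SD 2.51 with median scaling), and 4 went the other way. A single foreign source would move its genes together between MSC-1 arrays only if its share differed between them, which was not measured. The spread of the deviations of the 20 members higher in MSC-1 cells lay at percentile 44.2 of 10000 random level-matched sets. That spread is taken after the set's mean on each array is removed, so it does not measure a rise shared by the members. It therefore cannot tell a mixture from expression by the line. Most of the 20 members were highest on MSC-1 replicate 2, all but S100b, Cnp, Pax3, Lgi4 and Mag. The size of the rise varied, since Mbp had 4692 on that array against 2079 and 2190, and Sox10 had 1652 against 1569 and 1490. A rise on that array was not confined to the list, since Adh7 had 3510 against 1258 and 1811 and Serpine2 had 1352 against 775 and 710. Other genes higher in MSC-1 cells fell there, such as C4b with 289 against 1246 and 939 and Trf with 3503 against 4508 and 4337. Whether the members rose more often than other genes higher in MSC-1 cells was not tested.

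MSC-1 cells may lack Y-linked transcripts. All 6 probe sets of Ddx3y, Eif2s3y, Kdm5d and Uty in the authors' deposited table were at background on all 3 MSC-1 arrays. Their median log2 difference was 3.10 (SD 0.94 over the probe sets), though these probe sets too were chosen by their difference. In the deposited values the median over all 45037 probe sets was -0.0145, so no shift of all probe sets alike reached that size. The arrays had been scaled to a common mean, which largely sets that median beforehand. It therefore cannot decide on a dimness of the MSC-1 arrays before scaling. The lower quartile of the scaled signals was 5.31 to 5.55 on the MSC-1 arrays and 7.05 to 7.62 on the primary arrays. Y-linked genes outside that table were not analysed here, so a loss of the chromosome and a silencing of these 4 genes both stay open, untested.

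The 6 arrays can be split in 10 ways into 3 and 3, too few for a share under 0.05. The real split gave 18418 changed probe sets, 2810 at 4-fold, 2328 named genes and 1768 at 4-fold, each the highest count, reached by 1 split, and the highest of the other splits gave 0 in each case. Every other split mixes both groups on each side, so a wide group difference enters its residual spread and keeps its counts low. The counts of 0 were therefore largely set in advance and add no separate support.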
